A study of Mus musculus with 9 samples.

How the data were processed

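RNA from 2 mouse pancreatic ductal adenocarcinoma lines was profiled by a 3′ mRNA sequencing method that reads the end of each polyadenylated transcript. Per the labels, UN-KC-6141 (KC) carries mutant Kras and UN-KPC-961 (KPC) carries mutant Kras with mutant Trp53. Each line was edited with CRISPR/Cas9 against Ezh2 (EZH2KO) or carried a CRISPR control (CTR). The 9 libraries analysed here were 2 of KC_CTR, 2 of KC_EZH2KO, 3 of KPC_CTR and 2 of KPC_EZH2KO. The labels number the KC libraries from 2, and a replicate 1 of either KC group was not analysed here. Per the labels' protocols, libraries came from a QuantSeq forward kit with optional molecular identifiers and were sequenced as single reads. Whether the identifiers were used to collapse duplicates is not given in the sources used here. The extraction text in the labels speaks of liver tissue, whereas the sample labels name cell lines; the samples were treated as cell lines.

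The deposited table holds CPM values, read counts scaled to a common library total, for 20553 Ensembl gene IDs, with 1 column per library. Per the submitters' processing notes, the genome build was GRCm38. The aligner, the counting tool and the annotation are not given in the sources used here. Each column summed to the same total, and in every library the values were whole multiples of what 1 read is worth. Dividing by that step gave whole reads for 100% of values, within 0.01 of a read. The recovered depth was 2339464 to 3237357 reads per library, so that 1 read equalled 0.309 to 0.427 CPM. A gene without a read in a library could lie at up to 3 reads, 0.927 to 1.28 CPM. That floor and the read counts cover counting error only, since reads without collapsed identifiers are not independent molecules. Gene symbols were matched by ID for 20475 of the 20553 IDs, and 78 had none. Positions come from a GENCODE annotation on GRCm38.

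The test fixed before the data were examined was edgeR on counts, with limma on log2 values in its place for a normalized unit. Because the table holds CPM, limma was the main test. Values were transformed as log2(CPM + 1). Genes with at least 4 CPM in at least 2 libraries were kept, which left 10786. A single limma fit with an intensity trend took all 9 libraries with 1 mean per group, so that the spread between libraries was pooled over the 4 groups with 5 residual degrees of freedom and 5.2 prior degrees of freedom. The contrasts were KC_EZH2KO minus KC_CTR, KPC_EZH2KO minus KPC_CTR, the difference between these effects (the interaction, KPC effect minus KC effect), and KPC_CTR minus KC_CTR. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and every adjusted p in the text comes from this fit unless another tool is named. All tests were 2-sided. Log2 differences are on the log2(CPM + 1) scale with the SE of the fit, which understates changes of low genes. Folds are ratios of group mean CPM, and group values are mean ± SD. Against a group without a read the fold is a lower bound, with the group set at 3 reads over its libraries. No fold is given against a group with 1 to 3 reads.

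The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

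The 44 gene lists were written from textbook knowledge before the data were examined. The 37 with at least 5 tested members entered camera with a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over the lists of a contrast. Camera with an estimated correlation was run beside it and called no list in any contrast. Members were counted as called over all genes tested and adjusted over the list alone. The genes named in the text follow a rule set before the data were examined. It took, per contrast, the 10 largest called differences in each direction (5 for the interaction) among genes with a mean of at least 5 CPM and no overlap between the libraries compared (overlap was not checked for the interaction), leaving out predicted and unnamed genes. To these it added up to 4 members with the smallest p of each list described, and Ezh2, the other PRC2 members, Nfe2l2 and Keap1. Genes named outside it are said to be so.

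The alternatives planned before the data were examined were DESeq2 size factors, library totals alone (which is the main scaling here), DESeq2, limma-voom, no filter, a mean of at least 5 CPM, libraries thinned to the smallest total, only the groups compared in the fit, the replicate number as a block, pseudocounts of 0.1 and 5, an absolute log2 difference of at least 1, fry for the lists, and each library left out in turn. Where an omission left a group with 1 library, that library was assumed to vary like the other groups. Chosen after seeing the data were TMM scaling, totals without the ribosomal RNA features Gm42418, mt-Rnr1 and mt-Rnr2, variance weights per group, and edgeR's quasi-likelihood test on the recovered reads. That edgeR test called 282 genes higher and 242 lower in KC, 0 and 1 in KPC, 86 and 84 for the interaction, and 236 and 260 between the control lines. On recovered reads, limma-voom and DESeq2 were also run as alternatives.

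The fit was tested on simulated counts drawn from the real means and library sizes. Each simulated gene had 1 spread shared by all groups, so the larger spread of the KC_EZH2KO libraries was not reproduced. For the KC comparison, 10494 genes were run and 5.97%, 53.8% and 82.5% of genes changed by 1, 2 and 3 log2 units were called. For KPC the shares were 4.62%, 51.5% and 81.0% of the changed genes among 10499 run. The interaction recovered 0%, 7.81% and 40.0% among 10498 genes, and the control comparison 3.08%, 48.4% and 78.5% among 10472. Of the simulated calls, 6.19%, 8.16%, 8.82% and 6.59% in that order were unchanged genes. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9.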

Results

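Transcript ends were counted in KC and KPC pancreatic cancer cells with and without CRISPR editing of Ezh2, the gene for the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3. KC and KPC are mouse pancreatic tumour lines with mutant Kras, and KPC also carries mutant Trp53. The series asked how EZH2 shapes the transcriptome of these tumours and how EZH2 relates to NRF2, the transcription factor of the oxidative stress response that Nfe2l2 encodes. The KC libraries held 2838151 and 2632405 reads in the controls (replicates 2 and 3) and 2339464 and 2453950 in EZH2KO (replicates 2 and 3). The KPC libraries held 2652003, 2784942 and 2830434 reads in the controls (replicates 1, 2 and 3) and 2911987 and 3237357 in EZH2KO (replicates 1 and 2). Between 14132 and 14803 genes had at least 1 read in a library. Features of ribosomal RNA took 21.5% to 30.5% of each library's reads. Replicates of 1 group differed by more than counting noise, and no pair looked like repeat deposits of 1 library. Over the tested genes, KC_EZH2KO replicate 2 correlated better with KC_CTR replicate 2 (Pearson's r = 0.881) than with KC_EZH2KO replicate 3 (r = 0.862). The median SD of log2 values between replicates was 0.305 in KC_CTR, 0.418 in KC_EZH2KO, 0.302 in KPC_CTR and 0.177 in KPC_EZH2KO.

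Ezh2 itself (ENSMUSG00000029687, GRCm38 chromosome 6, 47530139 to 47595341, minus strand) was read in every library. In KC it fell 4.19-fold, from 472 and 327 CPM in the controls to 119 and 71.3 CPM in EZH2KO, a log2 difference of -2.08 ± 0.29 (adjusted p = 0.0043). In KPC it was 227, 246 and 245 CPM in the controls and 192 and 183 CPM in EZH2KO, a log2 difference of -0.35 ± 0.26 that did not pass the test (adjusted p = 1). The difference between the lines was 1.73 ± 0.39 log2 units (adjusted p = 0.051). Leaving out KC_EZH2KO replicate 2 took it past the threshold at 2.10 (adjusted p = 0.00817). A 3′ tag reads the transcript end, so an edit that stops the protein without lowering the mRNA leaves this value as it is. The KPC reads neither back nor contradict the label. The other core PRC2 subunits did not pass in either line. Suz12 differed by -0.68 ± 0.28 in KC and -0.30 ± 0.26 in KPC, and Eed by -0.62 ± 0.33 and 0.24 ± 0.30 (adjusted p of 0.205 and 0.315 in KC, 1 in KPC for both). Over all 12 listed PRC2 components camera gave an adjusted p of 0.122 in KC.

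**Figure D1:**
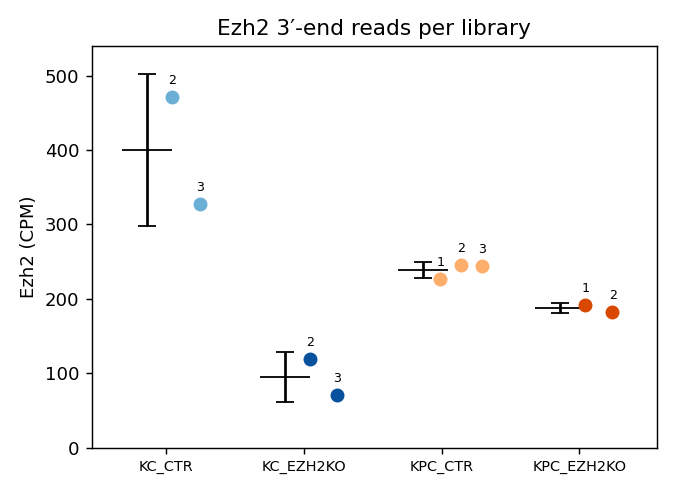
Ezh2 in CPM (vertical axis) in each library of the 4 groups, with the replicate number above each point and the group mean ± SD as a bar to its left. The KC EZH2KO libraries lay at 119 and 71.3 CPM, below the KC controls, and the KPC EZH2KO libraries at 192 and 183 CPM, below KPC controls between 227 and 246 CPM.

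In the KC line, 10 of 17 tested Hox genes and 10 of 24 mesenchymal genes rose in EZH2KO, while 9 of 22 epithelial genes and 11 of 18 genes of the classical pancreatic cancer programme fell. Hoxb9, Hoxb8, Hoxb4 and Hoxb7, neighbouring transcription factor genes of axial patterning (chromosome 11, 96271457 to 96276595 for Hoxb9 and to 96321638 for the end of Hoxb4), had no read in either control. They reached 111 ± 78, 50.1 ± 24.3, 25.8 ± 6.21 and 23.7 ± 4.51 CPM (SD, n = 2), at least 203-, 91.3-, 47- and 43.2-fold higher. Hnf4a, a transcription factor of gut and pancreatic epithelium, fell 59.2-fold from 76 ± 3.78 to 1.28 ± 1.81 CPM, and Krt19, the duct keratin, fell 12.3-fold from 875 ± 58.4 to 70.9 ± 45.5 CPM (SD, n = 2 each). The 4 list counts were 7, 3, 3 and 6 without KC_CTR replicate 3. They were 7, 4, 7 and 8 without KC_CTR replicate 2. Of 17 tested genes of RNA quality, immediate early response and dissociation, 0 were called by limma on all libraries (camera adjusted p = 0.481), but without KC_CTR replicate 2, 7 fell, and without KC_CTR replicate 3, 6 rose. Mitochondrial transcripts took 12.1% and 19.6% of the reads of KC_CTR replicates 2 and 3.

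In all, 277 genes were higher and 365 lower in KC EZH2KO by limma. Of all tested genes, 43.6% had no overlap between the libraries of the 2 groups, where chance gives 33.3%. At an unadjusted p under 0.05 there were 2281 genes where 539.3 would be expected with no difference. The median gene differed by -0.16 log2 units, and by -0.02 with TMM scaling, which called 336 genes higher and 313 lower, of which 272 and 312 were also called without it. These calls rest on the spread pooled over both lines. With only the 4 KC libraries in the fit, limma called 0 genes (1316 at an unadjusted p under 0.05) and edgeR called 0. With variance weights per group limma called 80 higher and 101 lower. The counts moved to 110 higher and 187 lower without KC_CTR replicate 2 and to 68 and 60 without KC_CTR replicate 3. They were 600 and 1047 without KC_EZH2KO replicate 2, 173 and 212 without KC_EZH2KO replicate 3, and 161 higher with 215 or 216 lower without KPC_EZH2KO replicate 1 or 2.

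Among the Hox genes 10 of 17 tested members rose and none fell (11 rose adjusted over the list alone; camera adjusted p = 2.1e-11, and adjusted p = 0.199 with an estimated correlation). DESeq2 called 4 Hox genes, without Hoxb7, Hoxb8 and Hoxb9, and limma-voom 6. Of 36 other developmental transcription factors that PRC2 typically silences, 6 rose and 5 fell (8 and 10 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.177). Without KC_CTR replicate 3 it was called higher (camera adjusted p = 0.00801) with 3 and 1 members called, and without KC_EZH2KO replicate 2, 9 rose and 9 fell. Foxd1 rose from no read to 23.8 ± 2.57 CPM, at least 43.4-fold. Pax3, a neural crest and muscle regulator, rose 25.2-fold to 40 ± 3.96 CPM, and Zic5 rose 13.6-fold to 31.7 ± 9.04 CPM, while Foxa2, a foregut endoderm factor, fell 4.15-fold to 37.7 ± 8.35 CPM (SD, n = 2). Genes described elsewhere as repressed by EZH2 in cancer did not move as a list, with 2 of 21 higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.587).

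Mesenchymal genes rose for 10 of 24 tested members, with none lower (12 higher adjusted over the list alone; camera adjusted p = 1.5e-13, and 0.188 as the adjusted p with an estimated correlation). Collagens and basement membrane genes rose for 6 of 26 (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.6e-10, and 0.188 as the adjusted p with an estimated correlation). The fibrillar collagen gene Col3a1 had 0.38 CPM in the controls and 499 ± 326 CPM in EZH2KO, a log2 difference of 8.39 ± 0.64 (adjusted p = 5.7e-04). Fstl1, a secreted glycoprotein, rose 112-fold to 358 ± 46.9 CPM, Col5a1 rose 21-fold to 176 ± 74.9 CPM, and Hspg2, the basement membrane proteoglycan perlecan, rose 4.5-fold to 103 ± 22.8 CPM. The fibroblast and stellate marker list moved the same way, with 2 of 7 members called (3 adjusted over the list alone; camera adjusted p = 6.8e-06, and 0.199 as the adjusted p with an estimated correlation). Without KC_EZH2KO replicate 2, 13 collagen and 4 fibroblast genes rose. Without KC_CTR replicate 2, as without replicate 3, they were 3 and 1, and 3 collagen genes rose without KC_EZH2KO replicate 3, KPC_EZH2KO replicate 1 or KPC_EZH2KO replicate 2. Part of this group stood much higher in KC_EZH2KO replicate 3 than in replicate 2. Thbs1, a matrix protein of the TGF-beta response, read 2291 against 61.6 CPM, Myh10 526 against 19.7, and Col1a1, which was not called, 486 against 10.7. Without replicate 3, Thbs1 (adjusted p = 0.0787) and Myh10 (adjusted p = 0.158) were no longer called. Across the 9 omissions their calls were lost in 7 and 6 (adjusted p up to 0.175 and 0.158). Without replicate 2, Col1a1 was called (adjusted p = 5.5e-04).

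The classical pancreatic cancer programme, a set of gut-type epithelial genes, fell for 11 of 18 tested members, and for all 18 adjusted over the list alone (camera adjusted p = 2.3e-14, and 0.188 as the adjusted p with an estimated correlation). Lgals4 fell 73.9-fold from 63.2 ± 39 to 0.855 ± 1.21 CPM. The mucin gene Muc1 went from 26.7 ± 13.8 to 0.204 ± 0.288 CPM and Anxa13 from 29 ± 2.34 to 0.214 ± 0.302 CPM, log2 differences of -4.45 ± 0.56 and -4.65 ± 0.46. Epithelial genes fell for 9 of 22 (15 adjusted over the list alone; camera adjusted p = 1.4e-07, and 0.188 as the adjusted p with an estimated correlation). The epithelial transcription factor Elf3 fell 22.9-fold to 1.06 ± 0.921 CPM. Cdh1, the E-cadherin gene, fell 12.9-fold from 948 ± 362 to 73.7 ± 75.4 CPM, a call lost without KC_CTR replicate 3 (adjusted p = 0.0772). By limma-voom 7 classical and 4 epithelial genes fell, and with variance weights per group 7 and 5. Ductal and ductal progenitor genes fell for 6 of 18 (10 lower and 1 higher adjusted over the list alone; camera adjusted p = 8.9e-05, and 0.199 as the adjusted p with an estimated correlation). Among them Car2, a carbonic anhydrase of ducts, fell 12.3-fold to 4.86 ± 3.41 CPM and Cd24a 4.08-fold to 80 ± 8.51 CPM.

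Of the 20 genes with the largest called differences in KC, the remaining higher ones were Ccn4, Prune2, Chst2, Serpine2 and the RNA-binding protein gene Igf2bp3. Igf2bp3 went from 0.176 to 64.3 ± 12.5 CPM (log2 difference 5.80 ± 0.31, adjusted p = 3.6e-05), and Ccn4 rose 296-fold to 213 ± 103 CPM. Serpine2 rose 91.3-fold, and Prune2 and Chst2 rose at least 123- and 119-fold from no read. The remaining lower ones were Il5ra, Rbp4, Tm4sf20, Lgals2, Vsig1, Tmigd1, Slc39a4 and Gipc2. Rbp4, the retinol carrier gene, fell 55.6-fold from 308 ± 169 to 5.54 ± 6.68 CPM, and Vsig1 fell 36.8-fold to 3.85 ± 5.44 CPM. Il5ra, a cytokine receptor subunit, fell 28-fold from 849 ± 237 CPM, with 59.4 and 1.22 CPM left in EZH2KO replicates 2 and 3. Without KC_CTR replicate 3 the calls of Il5ra, Lgals2, Tm4sf20 and Slc39a4 were lost (adjusted p = 0.0757, 0.074, 0.0505 and 0.0509). Without KC_CTR replicate 2 that of Il5ra was lost (adjusted p = 0.0863).

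Nfe2l2, Keap1 and the list of NRF2 targets were not called in KC. Nfe2l2 read 311 ± 57.9 CPM in controls and 312 ± 134 CPM in EZH2KO (log2 difference -0.05 ± 0.32, adjusted p = 0.947; 0.10 with TMM scaling), and Keap1, which holds NRF2 in check, differed by -0.31 ± 0.33 (adjusted p = 0.633). Of 41 tested NRF2 targets 1 rose and 4 fell (2 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 0.587). Without KC_EZH2KO replicate 2, 5 rose and 9 fell, and without KC_CTR replicate 3, 0 and 1. The 1 that rose was Sqstm1, an autophagy receptor gene. Gsta4, a glutathione transferase gene, fell 21.5-fold from 321 ± 171 to 14.9 ± 6.58 CPM. Gclc and Gclm, the subunit genes of the enzyme that starts glutathione synthesis, fell 5.88- and 2.43-fold, and Abcc4, an efflux pump gene, fell 4.63-fold. Without KC_CTR replicate 3 the calls of Gclc, Gclm and Abcc4 were lost (adjusted p = 0.0859, 0.0709 and 0.0751). Gclc also lost its call without KC_EZH2KO replicate 3 (adjusted p = 0.0643) and Gclm without KC_CTR replicate 2 (adjusted p = 0.0663). NRF2 regulators and partners were called higher as a list (2 of 17 rose and 1 fell, the same adjusted over the list alone; camera adjusted p = 0.039, and 0.199 as the adjusted p with an estimated correlation). Its called members were Sqstm1 and Bach2, which rose, and Dpp3, which fell, and each call was lost in 8 of the 9 omissions (adjusted p up to 0.241, 0.173 and 0.155). Without a filter on low values (camera adjusted p = 0.06) and without KC_CTR replicate 2 or KC_EZH2KO replicate 2 the list was no longer called (camera adjusted p = 0.326 and 0.101).

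Stress-response genes of the ATF4 and unfolded protein pathways rose for 7 of 39 members in KC (8 adjusted over the list alone; camera adjusted p = 8.6e-07, and 0.188 as the adjusted p with an estimated correlation). Trib3, Ddit3 and Atf5 rose 10.6-, 6.91- and 4.9-fold to 143 ± 94.8, 83.6 ± 28.7 and 365 ± 41.8 CPM. Without KC_CTR replicate 2 none of these passed (adjusted p = 0.0922, 0.0922 and 0.0709). Ddit3 did not pass either without KC_EZH2KO replicate 3 (adjusted p = 0.0827). Of the ATF4 list 0 rose without KC_CTR replicate 2, 3 without KPC_EZH2KO replicate 1 or 2 and 4 without KPC_CTR replicate 1, 2 or 3. The p53 target list was called higher (3 of 30 rose, 5 adjusted over the list alone; camera adjusted p = 1.1e-04, and 0.188 as the adjusted p with an estimated correlation). Its members Cdkn1a and Sesn2 each lost their calls in 8 of the 9 omissions (adjusted p up to 0.246 and 0.145), and Plk2, up 5.29-fold, in 1, without KC_CTR replicate 2 (adjusted p = 0.0645). Lists called with a higher camera statistic also included YAP and TEAD targets (5 of 24 rose and 3 fell, 9 and 4 adjusted over the list alone; camera adjusted p = 8.4e-04) and lysosome genes (2 of 35, the same adjusted over the list alone; camera adjusted p = 4.6e-04). TGF-beta response genes were the last of these (5 of 26 rose and 1 fell, 5 and 2 adjusted over the list alone; camera adjusted p = 0.0304), and TMM or DESeq2 scaling ended that call. All 3 had an adjusted p = 0.199 with an estimated correlation. Among the TGF-beta genes Id2, an inhibitor of differentiation factors, fell 10.2-fold from 433 ± 6.24 to 42.3 ± 10.9 CPM. Without KC_EZH2KO replicate 2, 7 p53, 9 YAP, 6 lysosome and 8 TGF-beta genes rose. These counts were 0, 1, 0 and 1 without KC_CTR replicate 2. Without KC_CTR replicate 3 they were 3, 0, 0 and 0. The YAP call was lost without KC_EZH2KO replicate 3 (camera adjusted p = 0.0618), the lysosome call without KC_CTR replicate 2 (camera adjusted p = 0.132), and the TGF-beta call without KC_CTR replicate 2 or KC_EZH2KO replicate 3 (camera adjusted p = 0.3 and 0.115).

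Proliferation lists were called lower in KC EZH2KO, and the mean levels of both lists differed between the KC controls. E2F and DNA replication genes fell for 2 of 44 members, Orc1 and Dhfr, and for 0 adjusted over the list alone (camera adjusted p = 5.7e-07, and 0.655 as the adjusted p with an estimated correlation). The Orc1 and Dhfr calls were lost in 7 and 5 of the 9 omissions (adjusted p up to 0.266 and 0.184). Without KC_EZH2KO replicate 2, 18 of the 44 fell, and 0 did without KC_CTR replicate 2, KC_EZH2KO replicate 3, KPC_CTR replicate 1 or KPC_EZH2KO replicate 1 or 2. DESeq2 called 7 lower. Mitosis genes had 0 called members of 40, also adjusted over the list alone, with a median log2 difference of -0.67 (camera adjusted p = 0.0404, and 0.825 as the adjusted p with an estimated correlation). Mean log2 levels of the mitosis list were 6.87 and 5.28 in KC_CTR replicates 2 and 3 and 5.86 and 5.0 in KC_EZH2KO replicates 2 and 3, and those of the E2F list 6.18, 4.6, 4.76 and 3.35 in that order. Without KC_CTR replicate 2 the E2F list was no longer called (camera adjusted p = 0.0628) and the mitosis list changed direction without a call (camera adjusted p = 0.336). With a pseudocount of 0.1 the mitosis list was not called (camera adjusted p = 0.0584). Its call was also lost without KC_EZH2KO replicate 3 or KPC_CTR replicate 1 (camera adjusted p = 0.557 and 0.053). The other 22 of the 37 lists were not called in KC, the lowest of their camera adjusted p-values being 0.0707.

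**Figure D2:**
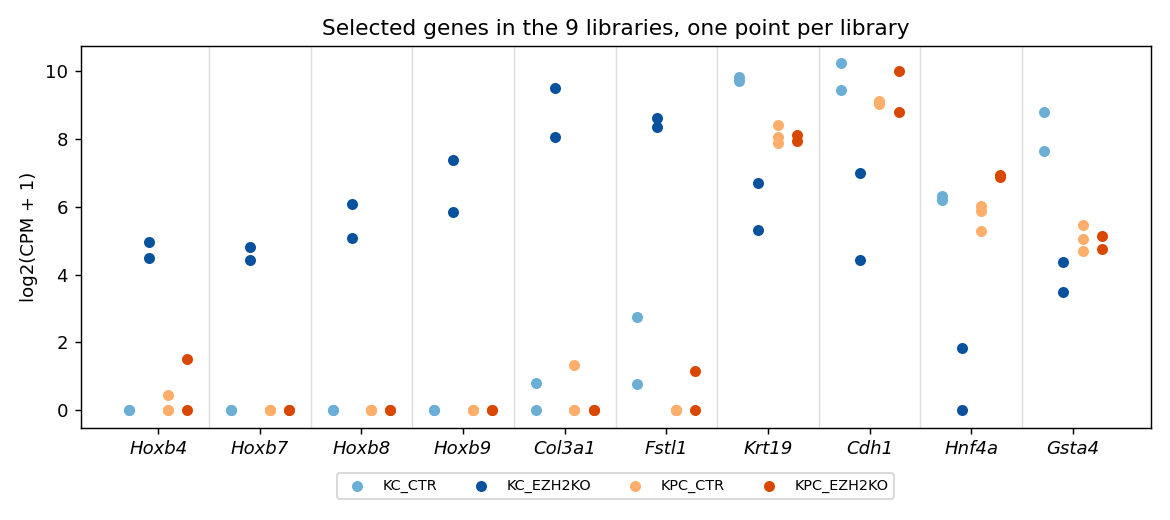
Levels of selected genes as log2(CPM + 1) (vertical axis) in each of the 9 libraries, with 1 column per gene, 1 point per library and 1 colour per group; some points overlap. Hoxb9 lay at 0 in both KC controls and at 111 CPM on average in KC EZH2KO, while Krt19 went from 875 to 70.9 CPM.

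In the KPC line, 3 genes passed the test, all lower in EZH2KO, and the mitosis genes as a list were lower with no member called by limma, a list call lost with an estimated correlation (adjusted p = 0.984). Mdfic encodes a protein with a MyoD family inhibitor domain (chromosome 6, 15720661 to 15802169). It had 27.1 ± 5.95 CPM in the controls (SD, n = 3) and 0.172 ± 0.243 CPM in EZH2KO (SD, n = 2). The log2 difference of Mdfic was -4.58 ± 0.32 (adjusted p = 4.6e-04). Cdyl2, a chromodomain protein gene (chromosome 8, 116574400 to 116732991), went from 11.5 ± 4.69 to 0.154 ± 0.218 CPM and Sipa1l2 (chromosome 8, 125418063 to 125569808) from 14.7 ± 6.58 to 0.481 ± 0.194 CPM. Their log2 differences were -3.38 ± 0.43 and -3.33 ± 0.42 (adjusted p = 0.0405 for each).

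By limma 0 genes were higher and 3 lower in KPC EZH2KO, with 550 genes at an unadjusted p under 0.05 where 539.3 would be expected. The edgeR test called 0 higher and 1 lower (608 at an unadjusted p under 0.05), limma-voom 0 and 0, and DESeq2 8 and 42. With variance weights per group limma called 23 and 60, and with only the KPC libraries in the fit limma called 0 and 0 (999 at an unadjusted p under 0.05) and edgeR 8 and 11. The calls of Cdyl2 and Sipa1l2 were each lost in 7 of the 9 omissions, at the highest without KPC_EZH2KO replicate 1 (adjusted p = 0.587 for both), and Mdfic was called in every one. The count of lower genes ran from 1 to 6 over the omissions and that of higher genes from 0 to 3.

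Of the 40 mitosis genes, 39 had a negative difference in KPC, with a median of -1.09 log2 units and no member called by limma, over all genes or adjusted over the list alone (camera adjusted p = 1.8e-19, and 0.984 as the adjusted p with an estimated correlation). With variance weights per group 2 mitosis genes were called lower, and with DESeq2 1. The topoisomerase gene Top2a, with the smallest p, had 249 ± 76.4 CPM in the controls and 77.1 ± 24.6 CPM in EZH2KO, a log2 difference of -1.66 ± 0.44 (adjusted p = 0.465). The mitotic kinase gene Plk1 had 38.9 ± 6.96 and 11.4 ± 3.52 CPM (log2 difference -1.70 ± 0.47, adjusted p = 0.538). Mean log2 levels of the list were 4.86, 5.23 and 4.46 in KPC_CTR replicates 1, 2 and 3 and 3.37 and 4.16 in KPC_EZH2KO replicates 1 and 2. Mitochondrial transcripts, a marker list of RNA quality, moved with these libraries in the opposite direction, with a median of 0.42 over 9 members and none called, also adjusted over the list alone (camera adjusted p = 0.00766, and 0.984 as the adjusted p with an estimated correlation). E2F and DNA replication genes had a median of -0.30 and no called member of 44, also adjusted over the list alone (camera adjusted p = 0.025, and 0.984 as the adjusted p with an estimated correlation). The mitochondrial list was not called without KPC_CTR replicate 2 or KPC_EZH2KO replicate 1 (camera adjusted p = 0.219 and 0.122). The E2F list was not called without KPC_CTR replicate 1 or 2 or KPC_EZH2KO replicate 1 (camera adjusted p = 0.0589, 0.304 and 0.122). Without a filter on low values neither was called (camera adjusted p = 0.0805 and 0.0647), nor was the E2F list with a pseudocount of 5 (camera adjusted p = 0.0683). The Hox, mesenchymal, epithelial and classical lists had no called member in KPC. Nfe2l2 differed by -0.05 ± 0.29 and Keap1 by 0.14 ± 0.30 (adjusted p = 1 for both), and both changed sign in single omissions. The other 34 lists were not called, the lowest of their camera adjusted p-values being 0.095.

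**Figure D3:**
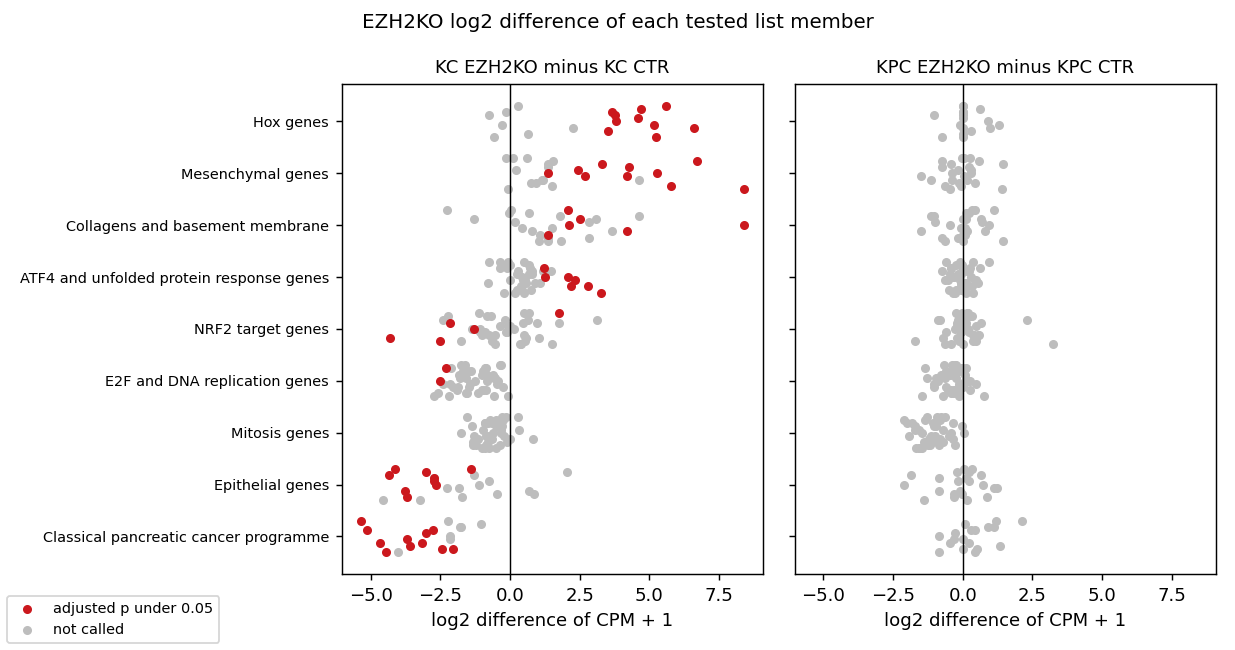
Log2 difference of CPM + 1 between EZH2KO and control (horizontal axis) for each tested member of 9 gene lists, in KC (left) and KPC (right), with genes at an adjusted p under 0.05 in red and the rest in grey. In KC, 10 Hox genes lay to the right and 11 classical genes to the left as called genes, and in KPC no member of these lists was called.

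Whether EZH2KO acted differently in the lines was tested as the interaction, KPC effect minus KC effect, so that a negative value stands for an EZH2KO effect that was lower in KPC than in KC. Hoxb9 (-6.61 ± 0.77), Hoxb8 (-5.59 ± 0.71), Col3a1 (-8.83 ± 0.87), Serpine2 (-8.69 ± 1.03) and Rora (-7.15 ± 0.92) had lower values in log2 units, with adjusted p-values from 0.00249 to 0.00614. Rora, a nuclear receptor gene, was at 3.19 and 115 CPM in KC control and EZH2KO and at 6.32 and 0.463 CPM in KPC. The highest values included Tmigd1 (7.55 ± 0.71, adjusted p = 0.00249), and Hnf4a had 6.53 ± 0.69 (adjusted p = 0.0027). Also among the 10 largest were Cmtm8 (7.79), Slco2a1 (7.28), Tm4sf20 (7.34), Lgals2 (6.89), Grem1, a secreted antagonist of bone morphogenetic proteins (-8.57), and Ccn4 (-6.84). Of these 6, each lost its call without KC_CTR replicate 3 (adjusted p = 0.0527, 0.0547, 0.0597, 0.13, 0.0536 and 0.061). The same 6 lost it without KPC_EZH2KO replicate 1 (adjusted p = 0.0549, 0.0662, 0.102, 0.0938, 0.0704 and 0.0676), and Lgals2 in 4 further omissions. Hoxb8, Hoxb9 and Col3a1 were not called by DESeq2, edgeR or limma-voom, and Serpine2 and Rora not by limma-voom. In KPC, Hoxb8 and Hoxb9 had no read in any library, and Col3a1 had 1.51 CPM in KPC_CTR replicate 1 alone. The interaction values of these genes thus rest on their rise in KC.

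By limma the interaction was higher for 145 genes and lower for 112, with 1786 at an unadjusted p under 0.05. DESeq2 called 219 and 301, edgeR 86 higher and limma-voom 23 and 31. The counts were 565 and 366 without KC_EZH2KO replicate 2, 100 and 62 without KC_CTR replicate 2, 13 and 34 without KC_CTR replicate 3. Leaving out control libraries of KPC gave 47 and 63 without KPC_CTR replicate 1 and 50 and 50 without KPC_CTR replicate 3. They were 9 and 19 without KPC_EZH2KO replicate 1, and 33 and 44 without KPC_EZH2KO replicate 2. Classical genes had a higher interaction for 8 of 18 members (16 adjusted over the list alone; camera adjusted p = 2.1e-14) and epithelial genes for 6 of 22 (13 adjusted over the list alone; camera adjusted p = 4.2e-06). Hox genes had a lower one for 6 of 17 (10 adjusted over the list alone; camera adjusted p = 1.3e-09) and mesenchymal genes for 4 of 24 (12 adjusted over the list alone; camera adjusted p = 1.2e-10). For all 4 lists the adjusted p was 0.273 with an estimated correlation. The classical, epithelial, Hox and mesenchymal counts were 14, 9, 10 and 9 without KC_EZH2KO replicate 2. They were 7, 1, 3 and 3 without KC_CTR replicate 2. Without KC_CTR replicate 3 they were 2, 0, 3 and 3. Omitting a KPC library gave 6, 1, 4 and 4 (KPC_CTR replicate 1), 6, 1, 3 and 3 (KPC_CTR replicate 3), 2, 0, 2 and 2 (KPC_EZH2KO replicate 1) and 3, 1, 5 and 3 (KPC_EZH2KO replicate 2). Among Hox genes edgeR called 0, limma-voom 0 and DESeq2 1. Of the classical and epithelial genes limma-voom called 1 and 1, and edgeR 6 and 3. Camera called 9 further lists for the interaction, of which the ductal list had 3 genes called higher (7 adjusted over the list alone; camera adjusted p = 9.3e-04, and 0.273 as the adjusted p with an estimated correlation). The others were the collagen, fibroblast, ATF4, p53, YAP and mitosis lists, lower, and the E2F and fatty acid lists, higher, with camera adjusted p-values from 2.3e-06 to 0.022 and adjusted p-values of 0.273 to 0.85 with an estimated correlation. The E2F call was lost without KC_CTR replicate 2 (camera adjusted p = 0.783) or KC_EZH2KO replicate 3 (camera adjusted p = 0.483), and the p53 and YAP calls without KC_EZH2KO replicate 3 (camera adjusted p = 0.111 and 0.102). The mitosis list lost its call without KC_EZH2KO replicate 2, KPC_CTR replicate 2 or KPC_EZH2KO replicate 1 (camera adjusted p = 0.322, 0.0864 and 0.395) and with a pseudocount of 5 (camera adjusted p = 0.0799), and changed direction without KC_CTR replicate 3 (camera adjusted p = 0.732). For the fatty acid list the call was lost without KC_CTR replicate 3, KC_EZH2KO replicate 2 or KPC_CTR replicate 3 (camera adjusted p = 0.172, 0.277 and 0.0615). The ductal count was 0 without KPC_EZH2KO replicate 1, 1 without KC_CTR replicate 3 and 5 without KC_EZH2KO replicate 2. NRF2 targets were not called as a list (camera adjusted p = 0.482). Its member Gsta4 had 4.16 ± 0.60 (adjusted p = 0.00966), lost without KC_CTR replicate 3 (adjusted p = 0.0506) or KPC_EZH2KO replicate 1 (adjusted p = 0.0662).

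No gene was called in the same direction in both lines. With 0 genes called higher and 3 lower in KPC, independent lists would share 0 and 0.102 genes, so the lack of overlap says nothing about whether the effects are shared. Counted as signs alone, 99 of the 277 genes higher in KC (35.7%) and 127 of the 365 lower ones (34.8%) had the same sign in KPC. Called genes without a read in KPC, such as Hoxb7, Hoxb8 and Hoxb9, have no direction there. The shares therefore do not tell how many genes went the opposite way. At an unadjusted p under 0.05 in KPC by limma, 8 of the genes higher in KC had the same sign and 21 the opposite. Of the lower ones 8 had the same sign and 26 the opposite. Across the 10786 genes the EZH2KO differences of the lines correlated with Pearson's r = -0.126 and Spearman's rho = -0.0985, a description across genes, which are not independent replicates. DESeq2 called 6 genes in both lines in the same direction and limma with variance weights per group 2.

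Between the control lines, KPC cells carried Cdkn2a, Cdkn2b and Peg3 transcripts that KC cells all but lacked, and KC cells carried Y-linked, Hoxa7 and Ubb transcripts that KPC cells all but lacked. Cdkn2a, the locus of the p16 and p19 tumour suppressors (chromosome 4, 89274471 to 89294653), read 883 ± 147 CPM in KPC (SD, n = 3) and 0.705 ± 0.997 CPM in KC (SD, n = 2), and its neighbour Cdkn2b (chromosome 4, 89306299 to 89311039) 145 ± 14.1 and 0.352 ± 0.498 CPM. Log2 differences were 9.14 ± 0.36 (adjusted p = 5.9e-07) and 6.80 ± 0.32 (adjusted p = 1.5e-06). The polyubiquitin gene Ubb was 207-fold lower in KPC, at 2.14 ± 1.85 CPM against 443 ± 4.09 CPM in KC. There is 1 line per genotype and the strain labels differ, so genotype, strain and line cannot be told apart here.

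In all, 242 genes were higher and 256 lower in KPC_CTR, with 2393 at an unadjusted p under 0.05. Without single KC libraries the counts were 65 and 69 (KC_CTR replicate 2), 77 and 83 (KC_CTR replicate 3), 460 and 485 (KC_EZH2KO replicate 2), 466 and 496 (KC_EZH2KO replicate 3). For KPC libraries they were 76 and 78 (KPC_CTR replicate 1), 78 and 99 (KPC_CTR replicate 3), 120 and 129 (KPC_EZH2KO replicate 1) and 119 and 122 (KPC_EZH2KO replicate 2). DESeq2 called 441 and 417. Among the largest higher genes were Wfdc2 (0.19 to 212 ± 17.6 CPM, log2 difference 7.50 ± 0.30), Igf2bp3 (0.176 to 113 ± 11.4 CPM, 6.61 ± 0.28) and Ifi202b, an interferon-inducible gene with no read in KC controls and 76.1 ± 28.4 CPM in KPC, at least 139-fold higher. Apob was 21.5-fold higher, at 130.2 ± 64.2 CPM. Y-linked Ddx3y, Kdm5d and Uty had 188 ± 21.4, 50.9 ± 10.7 and 44.8 ± 8.59 CPM in KC controls and 0.126, 0.126 and 0.237 CPM in KPC controls. En1, a homeobox gene of the developing brain, and Dio3, a thyroid hormone deiodinase gene, had 55 ± 19 and 34.6 ± 17.1 CPM in KC and no read in KPC, at least 152- and 95.5-fold lower. Adgrl2, Sdc2 and Flrt2 went from 74.6, 50 and 42.6 to 0.471, 0.707 and 0.471 CPM.

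Proliferation lists were called lower in KPC_CTR than in KC_CTR, and their levels also differed between the KC controls. E2F and DNA replication genes were lower in KPC for 7 of 44 members (15 adjusted over the list alone; camera adjusted p = 2.0e-09, and 0.884 as the adjusted p with an estimated correlation) and mitosis genes for 2 of 40 (13 adjusted over the list alone; camera adjusted p = 3.3e-08, and 0.884 as the adjusted p with an estimated correlation). Mean log2 levels of the mitosis list were 6.87 and 5.28 in KC_CTR replicates 2 and 3 against 4.86, 5.23 and 4.46 in KPC_CTR replicates 1, 2 and 3. Those of the E2F list were 6.18 and 4.6 against 3.81, 4.34 and 3.75. Of both lists 0 members were called without KC_CTR replicate 2, KPC_CTR replicate 1 or KPC_CTR replicate 3, and 1 of each without KPC_EZH2KO replicate 1 or 2. Without KC_EZH2KO replicate 2 or 3, 15 E2F genes were called, and without KC_CTR replicate 3 5 mitosis genes. DESeq2 called 16 and 15 and edgeR 11 and 6. Mcm6, a subunit gene of the replicative helicase, was 7.68-fold lower, at 17.6 ± 10.6 against 135 ± 73.7 CPM, and Birc5, the survivin gene, 8.3-fold, at 29.1 ± 11.9 against 242 ± 175 CPM. Those calls were lost without KC_CTR replicate 2 (adjusted p = 0.168 and 0.131), without KPC_CTR replicate 1 (adjusted p = 0.0826 and 0.076) and without KPC_CTR replicate 3 (adjusted p = 0.0692 and 0.0648), and Mcm6 also without KC_CTR replicate 3 (adjusted p = 0.0542). Genes of the ATF4 and unfolded protein pathways were higher for 8 of 39 members (12 adjusted over the list alone; camera adjusted p = 4.3e-06, and 0.859 as the adjusted p with an estimated correlation). The ATF4 count was 1 without KC_CTR replicate 2, 2 and 3 without KPC_CTR replicates 1 and 3, 4 without KPC_EZH2KO replicate 1 or 2 and 14 without KC_EZH2KO replicate 2 or 3. Sesn2, a stress-induced inhibitor of growth signalling, was 4.61-fold higher, at 70.2 ± 11.8 CPM, and Trib3 11.2-fold, at 152 ± 79.4 CPM, a call lost without KC_CTR replicate 2 (adjusted p = 0.0943).

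Hox genes were lower for 5 of 17 members (7 adjusted over the list alone; camera adjusted p = 0.0116, and 0.884 as the adjusted p with an estimated correlation), with a mean of -1.18 and a median of 0.00 log2 units. The Hox list was not called without KC_CTR replicate 3 (camera adjusted p = 0.0638), where 2 members were, without a filter on low values (camera adjusted p = 0.162) or with a mean of at least 5 CPM (camera adjusted p = 0.196). Without KC_CTR replicate 2 or KPC_CTR replicate 1, 3 Hox genes were called. The Hoxa10 call was lost in 4 of the 9 omissions (adjusted p up to 0.183) and that of Hoxa4 in 1 (0.061). Hoxa7 went from 31.2 ± 0.665 CPM to no read, at least 86.1-fold lower, and Hoxa5 from 34.9 ± 7.97 to 0.363 ± 0.0124 CPM, a log2 difference of -4.70 ± 0.48. Ductal genes were lower for 3 of 18 (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00598, and 0.884 as the adjusted p with an estimated correlation), a list call lost without KC_CTR replicate 3 (camera adjusted p = 0.0992). Dclk1, a kinase of tuft-like cells, went from 24.6 ± 15.5 CPM to no read, at least 67.9-fold lower. Imprinted genes were not called as a list (2 of 16 higher and 1 lower, 3 and 2 adjusted over the list alone; camera adjusted p = 0.357), but Peg3, which is read from the paternal copy, went from 0.176 to 634 ± 321 CPM and Sgce from 15.4 ± 10.4 CPM to no read. The Sgce call was lost without KC_CTR replicate 3 (adjusted p = 0.0724). Ribosomal protein genes, a marker list of RNA quality, were called lower (3 of 40, the same adjusted over the list alone; camera adjusted p = 0.00192), and lysosome and cholesterol synthesis genes higher (2 of 35 and 0 of 25, 2 and 0 adjusted over the list alone; camera adjusted p = 0.00397 and 0.00776), each with an adjusted p = 0.884 with an estimated correlation. Without KC_CTR replicate 2 the lysosome and cholesterol calls were lost (camera adjusted p = 0.375 and 0.636), and without KPC_CTR replicate 2 the cholesterol and ribosomal protein calls (camera adjusted p = 0.257 and 0.0517). The other 29 lists were not called, the lowest of their camera adjusted p-values being 0.0583. Ezh2 differed by -0.71 ± 0.26 between the controls (adjusted p = 0.151), Nfe2l2 by -0.36 ± 0.29 (adjusted p = 0.497) and Keap1 by -0.57 ± 0.30 (adjusted p = 0.296), and the NRF2 target Gsta4 was 9.56-fold lower in KPC (adjusted p = 0.00322).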

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

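The tests of foreign RNA, of a single library, of the Ezh2 level and of growth were chosen after the result was seen, whereas those of spread and of other splits were set before.

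The difference between the EZH2KO effects of the lines singled out 145 genes with a higher and 112 with a lower effect in KPC than in KC by limma. Among genes named for any comparison, the higher log2 interactions were Cmtm8 7.79, Tmigd1 7.55, Tm4sf20 7.34, Slco2a1 7.28, Lgals2 6.89, Rbp4 6.84, Hnf4a 6.53, Vsig1 6.38, Gipc2 5.88, Lgals4 5.43, Muc1 4.88, Cdh1 4.45, Anxa13 4.18, Gsta4 4.16, Krt19 3.67, Id2 3.37, Elf3 3.37, F3 3.35, Esrp2 3.24, Gclc 2.88, Cldn6 2.82, Foxa2 2.55, Cd24a 2.52 and Wwc1 2.20. The lower ones were Col3a1 -8.83, Serpine2 -8.69, Grem1 -8.57, Rora -7.15, Ccn4 -6.84, Hoxb9 -6.61, Foxd1 -6.34, Igf2bp3 -6.26, Fstl1 -6.15, Prune2 -6.04, Chst2 -5.73, Col5a1 -5.68, Hoxb8 -5.59, Sipa1l2 -5.39, Dlc1 -4.99, Mdfic -4.95, Hoxb7 -4.61, Zic5 -4.53, Pax3 -4.32, Hoxb4 -4.11, Cdyl2 -3.40, Atf5 -2.94, Plk2 -2.47, Inhba -2.30 and Fn1 -1.76. Of these calls, Cdh1 and Gclc were lost in 7 of the 9 omissions of a library (adjusted p up to 0.201 and 0.192), Plk2, Lgals2 and Atf5 in 6 (up to 0.210, 0.130 and 0.115) and Fn1 in 5 (up to 0.142). Ccn4, Cmtm8, Grem1, Gsta4, Krt19, Lgals4, Slco2a1 and Tm4sf20 were lost in 2 and Fstl1 in 1 (up to 0.102).

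The shift in KC EZH2KO from epithelial and classical genes to Hox, collagen and mesenchymal genes was weighed first. RNA from the KPC line is argued against, since 14 of the 21 genes that KC controls express and KPC controls do not reached 4 CPM in both KC EZH2KO libraries (0 of 21 in KPC EZH2KO), against 1 of the 15 with the opposite pattern. Fibroblast RNA is argued against by Dcn, Lum, Col1a2, Fap and Thy1, the highest of which, Col1a2, was at 5.30 CPM. All 7 tested members of the fibroblast and stellate list, however, had a positive difference with TMM scaling, 2 of them called. The low markers thus speak only against fibroblasts that express them. For a single KC_EZH2KO library as the whole cause, called members of the Hox, mesenchymal, epithelial and classical lists were counted. They numbered 32 without replicate 3 and 50 without replicate 2 (40 of 81 with both). These counts cannot decide, since each such omission takes the spread of that group, the largest, out of the pooled error. However, 10 Hox genes with at most 3 reads over the controls reached at least 5 CPM in each KC_EZH2KO library. For these genes that argues against a single library, and for the rest it stays open. The counts of 26 and 19 without KC_CTR replicates 2 and 3 leave open how much rests on single controls. The controls differed in immediate early and dissociation genes too (7 of 17 lower without replicate 2, 6 higher without replicate 3). The KC_EZH2KO libraries also stood apart, since replicate 2 correlated better with KC_CTR replicate 2 (Pearson's r = 0.881) than with KC_EZH2KO replicate 3 (r = 0.862). Loss of EZH2 stays open as the design's own explanation. So does a difference between edited and control cultures of this line unrelated to the edit, which no library here can test.

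The 642 calls in KC against 3 in KPC were weighed next. Both counts rest on the spread pooled over both lines. With variance weights per group limma called 80 higher and 101 lower in KC, and 23 and 60 in KPC. With only a line's own libraries limma called 0 genes in each line. In such fits edgeR called 0 in KC and 8 higher and 11 lower in KPC. The size of the gap thus depends on how the spread is estimated. The variance of the EZH2KO differences over that expected from each line's own spread was 2.37 in KC and 2.05 in KPC, which lies between the bounds set before, so a larger spread between the KC libraries cannot be told apart from a larger effect. A smaller loss of Ezh2 transcript in KPC may contribute, with an interaction of 1.73 ± 0.39 log2 units and an adjusted p of 0.051 that just misses the threshold, but transcript ends do not show how much protein was left. Of the 3 splits of the 4 KC libraries into pairs, the real one gave 642 calls and the highest other gave 0. These 3 splits are too few for a share under 0.05. Each other split also puts the difference between the real groups into the spread within its own groups. Few calls there were thus likely in advance, and the 0 does not exclude chance.

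Mitosis genes were lower in the KPC EZH2KO libraries by a mean of -1.08 log2 units, with no gene called by limma, 2 with variance weights per group and 1 with DESeq2. The list call was lost with an estimated correlation (adjusted p = 0.984), and mitochondrial transcripts, a marker list of RNA quality, moved the other way (median 0.42). Growth that differs between single cultures may account for the lower mitosis genes, since their mean level differed by 1.58 log2 units between the KC controls. These share a group but are of the other line. The ranges in KC_EZH2KO, KPC_CTR and KPC_EZH2KO were 0.859, 0.779 and 0.796, each smaller than the size of the KPC difference. Both KPC_EZH2KO libraries (3.37 and 4.16) lay below every KPC control (4.46 to 5.23). The KPC libraries alone thus give growth no such backing, and it stays open. An effect of EZH2 loss on division and a difference in RNA quality stay open and were not tested.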

How the results depend on the processing

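Results for TMM scaling, ribosomal RNA features left out, edgeR and variance weights rest on tests chosen after the data were seen; the rest were planned. Of the values for single genes and lists, 2133 kept direction and side of the threshold over the settings other than omissions, 294 no longer passed, 15 newly passed and 5 changed sign; over the omissions 1390 kept both, 254 no longer passed, 3 newly passed and 9 changed sign. A value for which an alternative gave no adjusted p was counted among the kept ones if its direction held. The 2133 can therefore overstate how many stayed on their side of the threshold. DESeq2 or TMM scaling, totals without ribosomal RNA features and an absolute log2 difference of at least 1 kept each count of called genes within 1.5 times. By limma the EZH2KO calls of both lines rested on the pooled spread. With the KC libraries alone 0 genes were higher and 0 lower and Ezh2, still at -2.08, was not called; with the KPC libraries alone 0 were lower, where edgeR called 8 higher and 11 lower. The cause was not tested. In simulations with the same spread in every group, that fit called 43.1% of KC genes changed by 2 log2 units. The real KC_EZH2KO libraries had the largest median SD, 0.418, so the simulation cannot tell why the real fit called 0. Where no reason is given below, the cause was not tested. At this depth 1 read is worth 0.309 to 0.427 CPM, a coarse step for low genes. In simulations of the KC comparison 5.97% of genes changed by 1 log2 unit were called, over genes of all levels and without varying depth.

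In KC, DESeq2 called 536 genes higher, limma-voom 178 higher and 123 lower, variance weights per group 80 and 101, and edgeR 242 lower. In KPC, DESeq2 called 8 higher and 42 lower, variance weights 23 and 60, a pseudocount of 5 gave 2 and 1, and a pseudocount of 0.1 gave 6 lower; edgeR, no filter and thinned libraries gave 1 lower each and limma-voom 0. The interaction counts were 219 higher and 301 lower with DESeq2, 23 and 31 with limma-voom, and 86 and 81 higher with edgeR and without a filter. Between the controls DESeq2 called 441 higher and 417 lower, no filter 131 and 167, and a mean of at least 5 CPM and a pseudocount of 0.1 gave 165 and 166 lower. Genes called in both lines numbered 6 with DESeq2 and 2 with variance weights.

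Over the omissions of 1 library, KC counts ran from 68 to 600 higher and 60 to 1047 lower, KPC counts from 0 to 3 and 1 to 6, the interaction from 9 to 565 and 19 to 366, the controls from 65 to 466 and 69 to 496, and genes called in both lines from 0 to 1. Ezh2 ran from -2.45 to -1.71 in KC and from -0.39 to -0.31 in KPC. An omission removes a library from its group, so its counts can fall in part by construction. They can also rise by construction where it takes a large spread out of the pooled error. The highest KC counts came without KC_EZH2KO replicate 2, from the group with the largest median SD (0.418). Counts between the controls also rose without either KC_EZH2KO library, although that group is not compared there.

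With an estimated correlation camera called 0 lists in every comparison. Fry on voom values asks whether a list's genes move one way and not whether they differ from other genes. In KC it called 3 lists higher and kept the count of lower lists within 1.5 times. It called 0 lists in KPC, for the interaction and between the controls. Without a filter 8 lists were lower in KC and 0 higher and 1 lower in KPC, and a pseudocount of 5 gave 1 lower in KPC. Over the omissions 7 to 13 lists were higher and 5 to 7 lower in KC, 0 to 2 and 1 to 3 in KPC, 4 to 6 and 7 to 12 for the interaction, and 1 to 8 and 5 to 9 between the controls.

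Values that changed sign were small or uncalled in the alternative. Nfe2l2 in KC was 0.126 with DESeq2 size factors, 0.103 with TMM, 0.164 with DESeq2, 0.146 with edgeR, 0.106 with limma-voom, 0.143 without KC_CTR replicate 2 and 0.401 without KC_EZH2KO replicate 3, with omissions down to -0.50. In KPC it was 0.026 without KPC_CTR replicate 1 and 0.12 without KPC_EZH2KO replicate 1, with omissions down to -0.22. Keap1 in KPC was -0.042 without KPC_CTR replicate 1 and also without KPC_EZH2KO replicate 2, with omissions up to 0.36. The mitosis list changed direction in KC without KC_CTR replicate 2 (camera adjusted p = 0.336; 1.7e-08 to 0.557 over the omissions) and for the interaction without KC_CTR replicate 3 (0.732, the highest, with 5.2e-08 the lowest). NRF2 targets in KC did so without KC_CTR replicate 3 (0.958, the highest, with 0.182 the lowest).

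The replicate numbers were not taken to pair the libraries, since no label ties them and deviations of the same-numbered KPC libraries correlated at only 0.0593 and 0.110. The 0.248 of both KC pairs is 1 value by construction. Each library with a same-numbered partner correlated best with it, a hint from the data, and a shared day stays open. With the replicate block, 306 genes were higher and 467 lower in KC, 0 and 2 in KPC, 84 and 84 for the interaction and 305 and 418 between the controls, and 2 lists were higher in KPC. Lower members of the E2F list then numbered 16 in KC and 20 between the controls, where 19 mitosis genes were lower, and the fatty acid list was not called for the interaction (camera adjusted p = 0.0572).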

Other observations

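The tests in this part were all chosen after their results were seen, and the genes named here were picked after their values were known.

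Genes silent in the KC controls and on in both KC EZH2KO libraries numbered 49, counting those with at most 3 reads over the controls and at least 5 CPM in each EZH2KO library. They included Hoxb3, Hoxb6, Hoxc6, Hoxc9, Hoxc13 and Hoxd8 besides the HoxB genes of the report, so that several clusters took part. Hoxc6 had no read in the controls and 15 and 89.2 CPM in EZH2KO, and Hoxb6 10.3 and 10.6 CPM. In all, 10 of the 49 were Hox genes and 1 was another developmental transcription factor of the lists.

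Y-linked genes were low in KC_EZH2KO replicate 2. Ddx3y, Kdm5d and Uty stood there at 11.1%, 10.4% and 19.3% of their mean in the other KC libraries, whereas their X-linked partners Ddx3x, Kdm5c and Kdm6a stood at 185%, 113% and 122%. Loss of the Y chromosome in part of that culture's cells may account for this, as the 3 measured genes were low together. Lower Y-linked transcription in all its cells would give such values too and was not tested. In replicate 3 Ddx3y was at 201 CPM, but Kdm5d at 33.4 and Uty at 23.2 CPM were below both controls (43.3 and 58.5, 38.8 and 50.9 CPM).

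Cdkn2a and Cdkn2b are textbook targets of Polycomb silencing, and both were all but absent in KC, with 5 and 2 reads over the 4 KC libraries. If EZH2 had kept them silent and was fully lost, they would have come on in KC EZH2KO, yet the highest value there was 0.408 CPM. That value cannot decide whether the silencing needs EZH2. Ezh2 was still read at 119 and 71.3 CPM in these libraries, and its protein was not measured. The neighbour Mtap was read in KC at 1014 CPM in controls and 1517 CPM in EZH2KO, against 279.7 and 249.2 CPM in KPC. A deletion of the Cdkn2a and Cdkn2b genes in KC is a possible explanation that expression values alone do not test. It would leave both genes unread with or without EZH2.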
